A study of Mus musculus with 6 samples.

How the data were processed

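RNA-seq of mouse liver was analysed from the deposited gene tables. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were prepared with a modified directional NEBNext Ultra II kit. The strand setting of the counting was not given in the sources used here. Per the submitters' processing notes, reads were aligned with STAR 2.7.7a to mm10 and edgeR was used, without a version given. The read counter and the annotation release were not given in the sources used here. The deposited table for the series held whole-number counts per Ensembl gene for 6 libraries, not normalised, with 55487 genes. The deposited per-sample values were a scaled signal, equal to the count times 1 constant per library, and covered the 30268 genes with a count in any library. Dividing them by the value of 1 read gave whole reads for 100% of values in each library (tolerance 0.001), all equal to the deposited counts. Their sums differed from those of plain CPM, so a further scaling had been applied. All per-sample columns were used.

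Libraries were grouped by the treatment and number in their titles into bortezomib 1 to 3 and control 1 to 3. Column names were matched to libraries through the names of the per-sample tables, and the columns of controls 2 and 3 are numbered 3 and 4. Of the gene IDs, 55141 had a symbol and 346 did not (15 of these were tested). Gene positions were taken from GENCODE M21 on GRCm38, the build called mm10, and span the whole gene. Each pair of libraries of the same group differed by more than sampling noise in a chi-square test of counts, so no library was counted as a repeat. Total counts were between 14908822 and 31377710, and 3 counts in a library correspond to 0.100 to 0.158 CPM. Intervals on counts are exact Poisson or binomial intervals at 95% and cover counting error only.

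Differential expression was tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test (glmQLFit and glmQLFTest with robust estimation) on the deposited counts. Genes were kept by filterByExpr, libraries were scaled by TMM, with factors from 0.867 to 1.28, and p-values were adjusted by Benjamini-Hochberg. The threshold was an adjusted p of 0.05. The fit had treatment as its only term and 4 residual degrees of freedom, with a common biological coefficient of variation of 0.455. All adjusted p-values for genes are from edgeR unless another tool is named. The SE of a log2 fold change is its absolute value divided by the square root of the F statistic. CPM values use the TMM-scaled library sizes. CPM of a group is given as mean ± SD over 3 libraries.

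Gene lists and cell type markers, 47 in all, were fixed before the data were examined, with the tests, the rule for named genes and the other processing settings. Each list was tested against other genes with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists. Of the 24 lists called that way (7 higher and 17 lower), 0 were called with an estimated correlation, where the lowest adjusted p was 0.621. For 23 of the 24 this was the highest adjusted p over the settings tried, and the male-biased list reached 0.737 with the Xist or Y term and bortezomib 3 left out. The test fry, which asks whether a list's genes move on balance in a direction and makes no comparison with other genes, called 7 lists. These were the immunoproteasome, heat shock, p53, interferon, cholangiocyte, Kupffer cell and sinusoidal endothelial lists. It did not call the proteasome subunit (fry adjusted p = 0.0530), integrated stress response (0.0903), bile acid synthesis (0.129), cholesterol synthesis (0.0989) or urea cycle (0.184) lists. Changes within a list were also counted adjusted over the list alone. Per-library list values are medians of log2 CPM minus the control mean.

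Named genes were chosen by rule: up to 8 genes higher and 8 lower with the largest absolute log2 fold change among those past the threshold, with at least 5 CPM in the higher group and no overlap between groups, leaving out predicted genes, clones and small RNA families. To these were added up to 4 members per list with the smallest adjusted p among those past the threshold, and Psmb5, Nfe2l1, Nfe2l2, Cyp7a1, Hspa1b and Alb in any case. Outside that rule, Psma5, Psme3, Shmt2, Abcb11, Akr1c6, Fasn, Mx2, Mfsd2a, Etnppl, Mup1, Mup7, Mup12 and Mup20, Xist, the Y-linked genes and members of the added lists were named after their values were seen. Some genes that the rule takes are not reported here. Genes with 1 to 3 control counts are given as ratios of scaled counts with a counting interval.

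The other settings chosen then were RLE, upper quartile and library total scaling, leaving out the 50 most abundant genes, no low-count filter or a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, limma-trend on the deposited values with a pseudocount of 1 or 0.1, no robust estimation, stricter thresholds, the replicate number as a block, an estimated correlation and each library left out. Chosen after seeing the data were a term for the Xist or Y pattern (in edgeR, DESeq2 and limma-voom, and with bortezomib 3 left out), the 4 libraries with high Xist alone, 6 further gene lists, and edgeR on the whole reads recovered from the deposited values, which called 2862 genes.

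The procedure was tested on simulated counts for this comparison, drawn from the control means, the library sizes and the trended spread of the real libraries. In them 14560 genes were tested and 200 changed. It recovered 0% of genes changed 2-fold, 44% at 4-fold, 96% at 8-fold and 100% at 16-fold (50 genes each), called 4 unchanged genes and gave 0 wrong signs. At 50% of the simulated spread it recovered 58% at 2-fold and 98% at 4-fold. A proteasome list shifted 2-fold had an adjusted p of 9.6e-16, and 0.0682 with an estimated correlation, and 0 other lists were called. With an estimated correlation the shifted list was thus missed. Genes were drawn independently, so the simulation does not test the effect of correlation within lists.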

Results

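Liver RNA of C57BL/6 mice was sequenced after treatment with bortezomib or with vehicle. Bortezomib is a reversible inhibitor of the proteasome, the protease complex that degrades ubiquitin-tagged proteins, and binds mainly the catalytic subunit encoded by Psmb5. The dose, the route and the time between treatment and collection were not given in the sources used here. Each group held 3 libraries, given in the series description as biological replicates, and the description gives the mice as male. Total gene counts were 27416012, 31377710 and 14908822 in bortezomib libraries 1 to 3 and 24870031, 21893547 and 23054201 in control libraries 1 to 3. Of 55487 genes in the table, 30268 had at least 1 count and 15375 passed the low-count filter and were tested. Values are CPM, counts scaled to the normalised library size, as mean ± SD with n = 3 per group, and log2 fold changes are bortezomib over control ± SE. Gene positions are whole gene spans on GRCm38 (mm10).

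The libraries parted by treatment along the first principal component, which held 57.4% of the variance. Bortezomib 1 and 2 resembled each other, with r = 0.982 across genes, and bortezomib 3 stood apart from them, with r = 0.888 and 0.881. The second component, with 23.2% of the variance, separated bortezomib 3 from the other 5 libraries. Hepatocyte markers had a median log2 difference from the control mean of -2.04 in bortezomib 3, against -0.21 and -0.21 in bortezomib 1 and 2. Sex-linked transcripts did not match the male sex given in the series description in 4 of the 6 libraries. Xist, the RNA that silences an X chromosome in female cells, was at 517, 321 and 1759 CPM in bortezomib 1 to 3 and at 478 CPM in control 1, but at 0.580 and 4.42 CPM in controls 2 and 3. The summed level of 4 Y-linked genes (Ddx3y, Uty, Eif2s3y and Kdm5d) was 175 and 349 CPM in controls 2 and 3 and between 0.368 and 1.29 CPM in the other 4 libraries, at most 0.733% of the lower of those controls. The treated group therefore held no library with the Y-linked transcripts, and 2 of 3 controls had them.

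**Figure D1:**
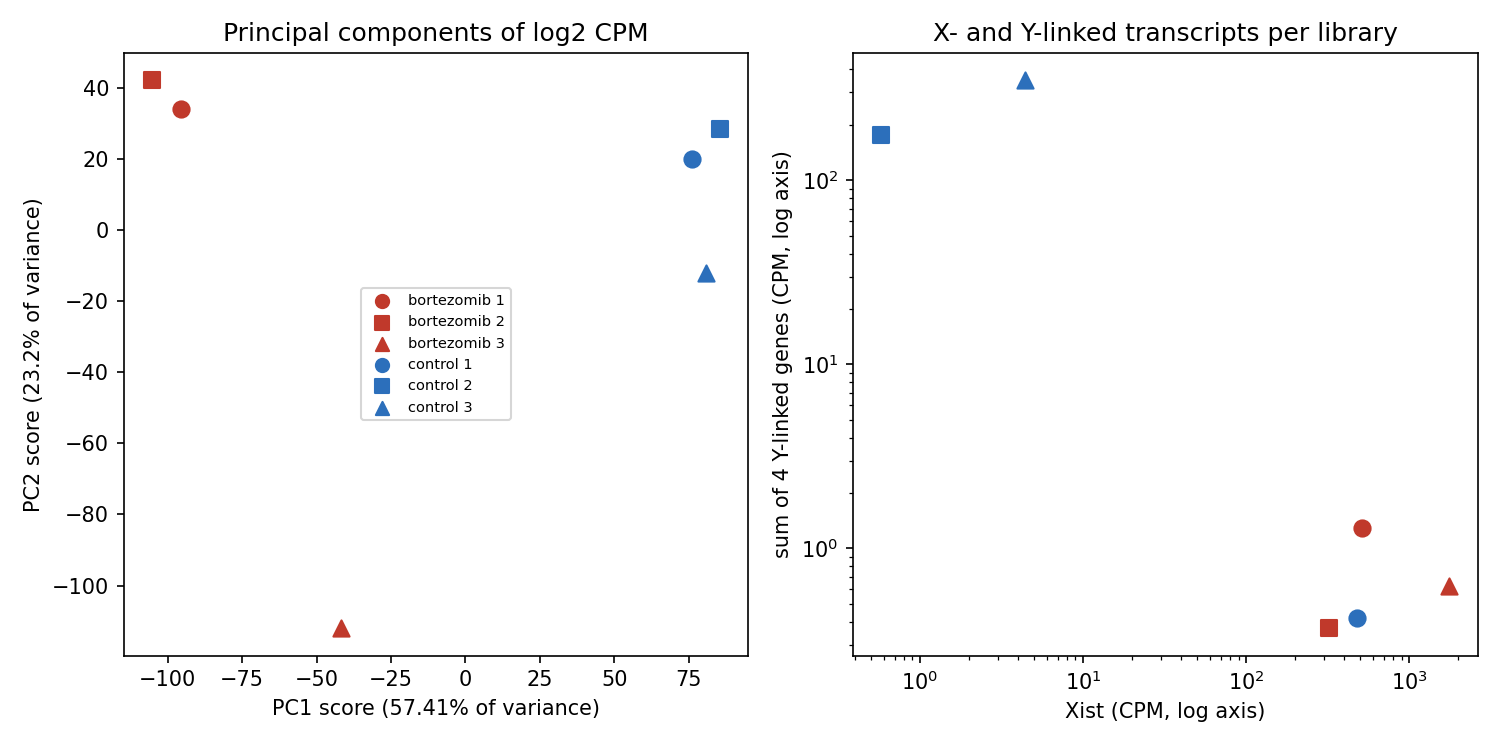
Left, scores of the 6 libraries on the first and second principal components of log2 CPM (57.4% and 23.2% of the variance); right, CPM of Xist against the summed CPM of 4 Y-linked genes on log axes. Points are single libraries, coloured by group with a marker per replicate number: bortezomib 3 lies apart on the second component, and controls 2 and 3 alone have Y-linked levels of 175 and 349 CPM.

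In livers of bortezomib-treated mice 12 of 21 heat shock response genes, 14 of 32 proteasome subunit genes and 12 of 23 integrated stress response genes rose. In the other direction, 5 of 18 bile acid synthesis genes, 8 of 25 cholesterol synthesis genes, 4 of 22 urea cycle and amino acid breakdown genes and 18 of 33 interferon-stimulated genes fell. Each of these lists differed from other genes in camera with a preset correlation, but not when the correlation was estimated (adjusted p = 0.621 for each with an estimated correlation). Before adjustment, their camera p with an estimated correlation lay between 0.0768 (interferon) and 0.287 (urea cycle). The shared 0.621 comes from the adjustment over lists. In simulation a list shifted 2-fold also missed the threshold that way (adjusted p = 0.0682). Missing it therefore does not show that a list was unchanged. Without 1 library at a time these counts were 0 to 13, 0 to 16 and 3 to 15 for the rises and 2 to 7, 4 to 11, 0 to 5 and 4 to 20 for the falls. The highest of each came without bortezomib 3, and the lowest without control 1 or 2 or bortezomib 1 or 2. The constitutive chaperone Hspa8 (chromosome 9, 40800984 to 40810087) went from 916 ± 251 CPM in controls to 9979 ± 1022 CPM in treated livers, a rise by 3.44 ± 0.47 on the log2 scale (adjusted p = 0.00904), though the call was lost without control 1. Cyp7a1 (chromosome 4, 6265612 to 6275633), the rate-limiting enzyme of bile acid synthesis, fell from 139.6 ± 36.8 to 5.34 ± 4.25 CPM (log2 fold change -4.70 ± 0.70, adjusted p = 0.0104; -5.52 without bortezomib 1). With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment at 0.05, 2862 of 15375 tested genes changed, 1631 higher and 1231 lower in treated livers. Upper quartile scaling called 1211 higher and 1512 lower, so the share of higher calls was 57.0% with the main scaling and 44.5% with that one. Relative to the main scaling, whose median log2 fold change over all tested genes was 0.04, the median was -0.15 with upper quartile scaling and 0.16 with library totals. The groups did not overlap for 6373 genes, 41.5% of those tested, where chance gives 10%.

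That count depended on single libraries. It was 484 and 517 without bortezomib 1 or 2, 6702 without bortezomib 3, and 330, 348 and 1349 without control 1, 2 or 3. At an unadjusted p under 0.05 edgeR had 4353, 4229 and 8319 genes without bortezomib 1, 2 or 3. Without control 1, 2 or 3 it had 4213, 4707 and 5445, against 5613 with all libraries. Each of these fits had 3 residual degrees of freedom instead of 4. All of the 2862 genes kept their direction in each fit (100%), though they were chosen with all libraries, which favours this. With a term for the Xist or Y pattern, added after seeing the data, edgeR called 0 genes (2798 at an unadjusted p under 0.05), limma-voom 0 (2898) and DESeq2 1180. With that term and bortezomib 3 left out edgeR called 3145. Of the 2862 genes, 99.8% kept their direction with that term in edgeR. Their median absolute log2 fold change was 1.92 without and 1.96 with it, while their median SE went from 0.406 to 0.625. All treated libraries had high Xist, so the term sets them against control 1 alone. The genes were chosen with control 1 among the controls, which favours a kept direction and size. Of 133 named genes called, 51, 48 and 129 were still called without bortezomib 1, 2 or 3 and 38, 38 and 73 without control 1, 2 or 3. Of the 133, 26 kept the call without any single library, and those given by name are described as held in all leave-one-out fits.

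Proteasome subunit genes stood higher in treated livers. All 32 constitutive subunits had a positive fold change, with a median of 1.25, and 14 rose while 18 did not pass (25 rose adjusted over the list alone). With adjustment over all tested genes, the risers were mostly subunits of the regulatory particle, which unfolds substrates. Psmd1 (chromosome 1, 86064387 to 86139151) had 306 ± 14.8 CPM in treated livers and 86.7 ± 14.2 CPM in controls (log2 fold change 1.82 ± 0.31, adjusted p = 0.0133), Psmd11 (chromosome 11, 80428615 to 80473248) had a log2 fold change of 1.62 ± 0.32 and Psmd12 (chromosome 11, 107479484 to 107504362) of 1.50 ± 0.31. Of the core particle genes only the alpha subunit Psma5 passed (log2 fold change 1.85 ± 0.43, adjusted p = 0.0277). Adjusted over the list alone, more core particle genes rose, so this emphasis depends on the adjustment. Psmb5 (chromosome 14, 54614119 to 54618022), the subunit bound by the drug, had 70.9 ± 24.5 CPM in treated livers and 43.1 ± 8.06 CPM in controls and did not pass (log2 fold change 0.72 ± 0.33, adjusted p = 0.160). The list differed from other genes in camera with a preset correlation of 0.01 (adjusted p = 5.0e-08), but not when the correlation was estimated (adjusted p = 0.621 with an estimated correlation). Over its alternatives the adjusted p went from 5.9e-11 to 0.621. The list median was 1.02, 0.91 and 1.56 in bortezomib 1 to 3, relative to the control mean. Without bortezomib 3, 16 subunits rose, and without any other single library 0 or 1 did. Psmd11, Psmd12 and Psma5 kept their calls only without bortezomib 3, and Psmd1 only without bortezomib 3 or control 3.

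The immunoproteasome went the other way. Of 6 genes for its catalytic subunits and the PA28 activator, 5 fell and 0 rose (the counts were equal adjusted over the list alone). The median log2 fold change was -1.19. Psmb9 (chromosome 17, 34181987 to 34187764), an interferon-inducible catalytic subunit, went from 29.4 ± 2.96 to 4.76 ± 1.31 CPM (log2 fold change -2.63 ± 0.32, adjusted p = 0.00832), held in all leave-one-out fits. Psmb8 (chromosome 17, 34197721 to 34201454) had a log2 fold change of -1.32 ± 0.30 and Psmb10 (chromosome 8, 105935735 to 105938444) of -1.22 ± 0.33, while Psme3 was at 0.60 ± 0.35 and did not pass (adjusted p = 0.247). The list's camera adjusted p was 0.0166, against adjusted p = 0.621 with an estimated correlation, and the list was not called without bortezomib 3 (median -1.12). Among assembly and recovery factors of the proteasome system, 4 of 18 rose and 0 fell (4 and 0 adjusted over the list alone). They were Zfand2a (chromosome 5, 139471211 to 139484549; log2 fold change 4.40 ± 0.56, adjusted p = 0.00844, held in all leave-one-out fits), a heat-shock-inducible proteasome partner, Zfand5 (log2 fold change 2.39 ± 0.45, adjusted p = 0.0167), and the p97 cofactors Nploc4 and Ufd1 (1.84 ± 0.43 and 1.90 ± 0.26). That list was not called (adjusted p = 0.0842), except without bortezomib 2 (median 0.48) or control 2 (0.52). Nfe2l1 (chromosome 11, 96817414 to 96829968), which encodes a transcription factor of proteasome genes, was at -0.63 ± 0.33 and did not pass (adjusted p = 0.204). Of 15 ubiquitin genes and autophagy receptors, 4 rose (4 adjusted over the list alone), with Sqstm1 (chromosome 11, 50199366 to 50210827), the p62 receptor, at 3761 ± 1087 CPM in treated livers and 346 ± 128 CPM in controls (log2 fold change 3.44 ± 0.51, adjusted p = 0.0104) and the polyubiquitin gene Ubb (chromosome 11, 62551171 to 62553213) at 2.69 ± 0.57. The list as a whole was not called (adjusted p = 0.0842), except with library totals (median 0.72), the replicate block (0.48), without bortezomib 3 (0.61, and 0.80 with the Xist or Y term as well) or without control 2 (0.68). Sqstm1 and Ufd1 lost their calls without control 1 (of all 6 leave-one-out fits), and proteasome genes have processed pseudogenes that can share reads. Without bortezomib 3, 5 immunoproteasome genes fell, and without any other single library 1 or 2 did. For the assembly and ubiquitin lists, 4 and 7 rose without bortezomib 3 (0 and 1 fell), and 1 to 2 and 0 to 1 without any other. Psmb8, Zfand5, Nploc4 and Ubb kept their calls only without bortezomib 3, and Psmb10 only without bortezomib 3 or control 3.

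**Figure D2:**
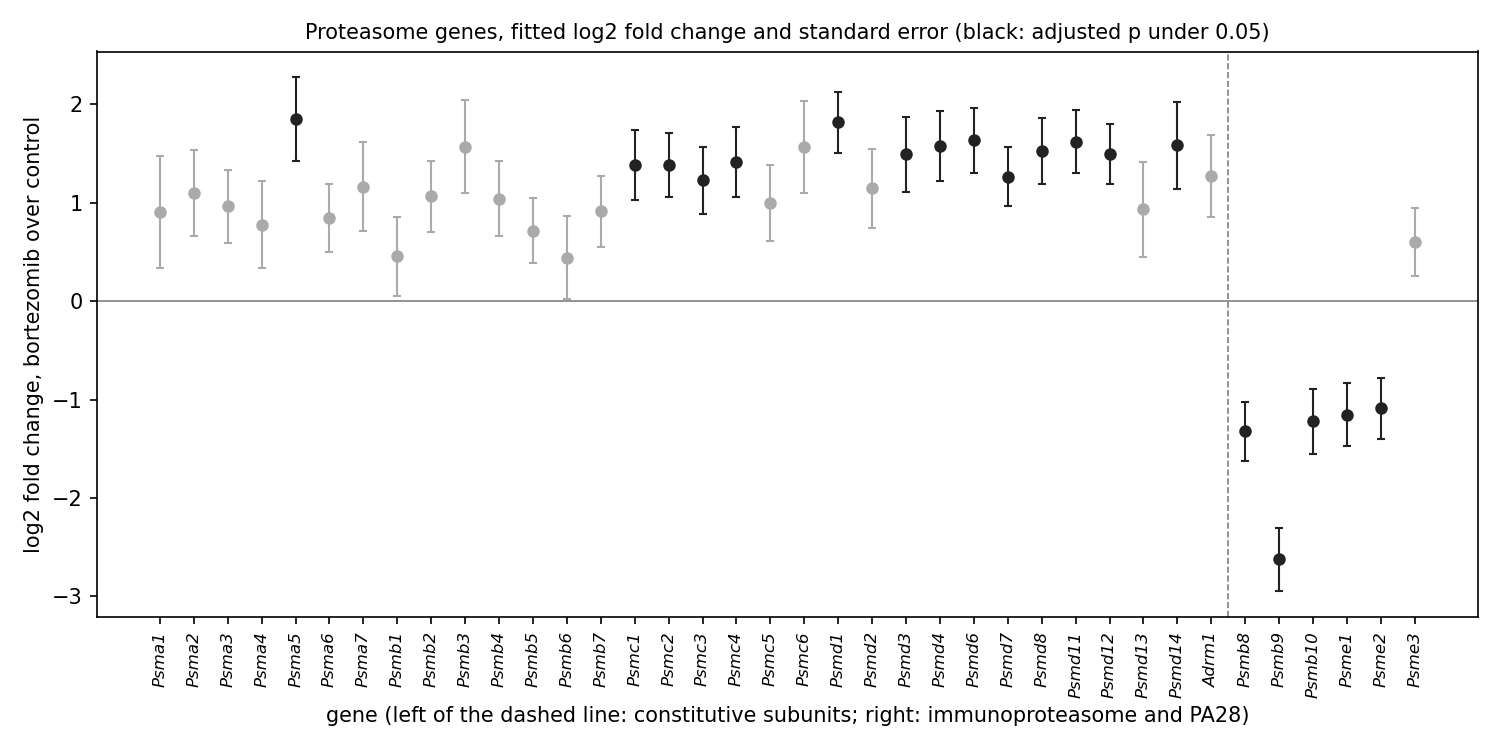
Fitted log2 fold change of bortezomib over control (points) with its standard error (bars) for 32 constitutive proteasome genes, left of the dashed line, and 6 immunoproteasome and PA28 genes, right of it; black marks an adjusted p under 0.05. All 32 constitutive genes lie above 0, with 14 in black, and 5 of the other 6 lie below 0, all 5 in black.

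Several chaperone and stress response genes rose. Among heat shock response genes, 12 of 21 tested members rose and 0 fell (15 and 1 adjusted over the list alone), with a median of 1.52. Besides Hspa8 these included the co-chaperone Dnajb1 (chromosome 8, 83608193 to 83612653; log2 fold change 2.20 ± 0.30, adjusted p = 0.00904), Hsph1 (chromosome 5, 149614287 to 149636376; 2.37 ± 0.41), Bag3 (chromosome 7, 128523616 to 128546981; 2.22 ± 0.46) and the inducible chaperone Hspa1b (chromosome 17, 34956436 to 34959238), at 26.7 ± 14.7 CPM in treated livers and 4.71 ± 3.43 CPM in controls (log2 fold change 2.51 ± 0.62, adjusted p = 0.0325), whose reads can be shared with its near-identical copy Hspa1a. Among the 6 leave-one-out fits, Hspa8 and Dnajb1 lost their calls without control 1, and Hsph1 without control 1 or bortezomib 1 or 2. Of 23 integrated stress response genes, the programme downstream of the translation factor eIF2 and Atf4, 12 rose and 1 fell (14 and 2 adjusted over the list alone), with a median of 2.71. Psat1 (chromosome 19, 15904678 to 15947337), an enzyme of serine synthesis, went from 1.02 ± 0.311 to 34.7 ± 7.50 CPM (log2 fold change 5.07 ± 0.38, adjusted p = 0.00551). The amino acid transporter genes Slc3a2 (chromosome 19, 8706882 to 8723369; 2.87 ± 0.39) and Slc7a11 (chromosome 3, 49892526 to 50443614; 5.06 ± 0.64) rose as well, and the calls of all these 3 held in all leave-one-out fits. Slc7a11 had 185 counts over the treated libraries and 5 over the controls, so the size of its rise rests on few control reads. The member that fell was Shmt2 (-1.35 ± 0.38), of mitochondrial serine metabolism. Both lists were called against other genes (camera adjusted p = 1.2e-05 and 4.2e-04), with adjusted p = 0.621 for both with an estimated correlation. Bortezomib 3 differed from its group in this programme: Atf3 (chromosome 1, 191170296 to 191218039), a stress-induced transcription factor, was at 556 and 595 CPM in bortezomib 1 and 2, at 6.23 CPM in bortezomib 3 and at 2.39 ± 1.14 CPM in controls. The list median was 2.83, 3.20 and 0.58 in bortezomib 1 to 3. Without bortezomib 3, 13 heat shock and 15 integrated stress response genes rose (1 and 2 fell), and without any other single library 0 to 4 and 3 to 6 did. Bag3, Hspa1b and Atf3 kept their calls only without bortezomib 3, and Shmt2 only without bortezomib 3 or control 3. Slc7a11 was at 5.68 without control 1 and Hspa1b at 3.28 without control 2.

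The other stress lists moved less uniformly. Of 21 genes of the unfolded protein response of the endoplasmic reticulum, 2 rose (2 adjusted over the list alone): the chaperone Hspa5 (chromosome 2, 34771970 to 34777547), from 878 ± 276 to 6416 ± 742 CPM (log2 fold change 2.87 ± 0.46, adjusted p = 0.0118), and its partner Dnajb9 (chromosome 12, 44205559 to 44210326; log2 fold change 2.04 ± 0.36, adjusted p = 0.0145). That list was not called (adjusted p = 0.389). Of 30 targets of NRF2, the regulator of antioxidant genes, 9 rose and 0 fell (9 and 0 adjusted over the list alone). They included the glutathione transferase Gsta1 (chromosome 9, 78230656 to 78242684), at 99.4 ± 84.8 CPM in treated livers and 0.620 ± 0.344 CPM in controls (log2 fold change 7.33 ± 0.88, adjusted p = 0.00819), the peroxiredoxin-repair gene Srxn1 (chromosome 2, 152105516 to 152111376; 4.91 ± 0.71) and the export pump gene Abcc4 (chromosome 14, 118482692 to 118706219; 2.88 ± 0.39). Gsta1, which has close paralogs, and Abcc4 held in all leave-one-out fits. Nfe2l2 (chromosome 2, 75675513 to 75704641), which encodes NRF2, was at 0.07 ± 0.27 (adjusted p = 0.868). The NRF2 list had a median log2 fold change of 1.003 and per-library medians of 0.30, 0.13 and 1.45 in bortezomib 1 to 3, and was not called without bortezomib 3 (median 0.14, and 0.24 with the Xist or Y term as well) or control 3 (0.80). Of 4 metallothionein and zinc transport genes 3 rose (3 adjusted over the list alone), with Mt1 (chromosome 8, 94179082 to 94180327) at 2199 ± 1291 CPM in treated livers and 273 ± 228 CPM in controls; the list was not called without bortezomib 1 (median 2.34) or control 3 (2.57), with the Xist or Y term (2.26) or in the 4 libraries with high Xist (2.22). Of 19 p53 targets 5 rose and 1 fell (7 and 1 adjusted over the list alone). Mdm2 (chromosome 10, 117688875 to 117710758), the ubiquitin ligase of p53, had a log2 fold change of 2.57 ± 0.37, and Ei24 (chromosome 9, 36779159 to 36797393), an endoplasmic reticulum protein gene, of -1.75 ± 0.29. The p53 list was not called without bortezomib 3 (median 1.10, and 0.93 with the Xist or Y term as well) or control 3 (1.40). Camera adjusted p was 0.00419, 0.0362 and 0.0268 for the NRF2, metallothionein and p53 lists, and adjusted p = 0.621 for each with an estimated correlation. Without bortezomib 3, 3, 10, 4 and 10 members rose in the unfolded protein response, NRF2, metallothionein and p53 lists, and 4, 2, 0 and 1 fell. With another library left out 0 to 2, 3 to 5, 0 and 0 to 1 rose. Hspa5, Srxn1 and Mdm2 lost their calls without control 1 or 2, and Dnajb9 without control 1 or bortezomib 1. Mt1 kept its call only without bortezomib 3, and Ei24 only without bortezomib 3 or control 3. Gsta1 and Srxn1 were at 6.37 and 3.92 without bortezomib 3, and Mt1 went from 3.01 to 3.95 without control 1.

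Several genes of bile acid and sterol metabolism fell. Of 18 bile acid synthesis genes 5 fell and 0 rose (8 and 0 adjusted over the list alone), with a median of -1.19. Besides Cyp7a1, whose call held in all leave-one-out fits, these were Amacr (chromosome 15, 10981756 to 10996626; log2 fold change -2.85 ± 0.41, adjusted p = 0.0101, also held), a side-chain racemase, the conjugating enzyme gene Baat (chromosome 4, 49489422 to 49506557; -2.89 ± 0.48) and the paralogs Akr1c6 and Akr1c14 (-3.18 ± 0.86 and -4.22 ± 0.74). Of 19 bile acid transporters and receptors 4 fell and 1 rose (6 and 1 adjusted over the list alone). The canalicular bile salt pump gene Abcb11 went from 889 ± 192 to 154 ± 78.1 CPM (log2 fold change -2.53 ± 0.51, adjusted p = 0.0199). Nr0b2 (chromosome 4, 133553376 to 133556536), the repressor SHP induced by bile acids, went from 46.1 ± 28.6 to 0.802 ± 0.564 CPM (log2 fold change -5.80 ± 0.84, adjusted p = 0.0103), held in all leave-one-out fits, and Nr5a2 (chromosome 1, 136842571 to 136960448) was at -1.73 ± 0.27. The riser was Abcc4. Of 25 cholesterol synthesis genes 8 fell and 0 rose (8 and 0 adjusted over the list alone), with a median of -1.34. Hmgcs1 (chromosome 13, 119690379 to 119708260), an early enzyme of the pathway, went from 427 ± 154 to 37.0 ± 8.78 CPM (log2 fold change -3.53 ± 0.44, adjusted p = 0.00838). Idi1 (chromosome 13, 8885501 to 8892451; -5.15 ± 0.69) and Acat2 (chromosome 17, 12942890 to 12960747; -3.33 ± 0.48) fell too, and these 3 held in all leave-one-out fits. In control 1, the control with high Xist, Idi1 was at 35.5 CPM, against 127 and 178 CPM in controls 2 and 3. Camera adjusted p was 9.6e-04, 0.0360 and 1.2e-05 for the synthesis, transport and cholesterol lists, against adjusted p = 0.621 for each with an estimated correlation. The falls were larger in bortezomib 3 (medians -2.40, -1.36 and -2.53), whose hepatocyte markers were also lower, and without that library the first and second lists were not called (medians -0.85 and -0.56). Without it and with the Xist or Y term, none of the 3 lists was called (-0.70, -0.56 and -0.64). Without bortezomib 3, 7, 6 and 11 members of the 3 lists fell and 1, 2 and 1 rose. With another library left out 2 to 4, 1 to 3 and 4 to 7 fell. Baat lost its call without bortezomib 1 or control 1 or 2, and Akr1c14 without bortezomib 2 or control 2. Akr1c6 kept its call only without bortezomib 3, and Abcb11 and Nr5a2 only without bortezomib 3 or control 3. Akr1c6 and Akr1c14 were at -4.19 and -5.18 without bortezomib 1, and Acat2 at -3.96 without bortezomib 3.

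Lipid, sugar and amino acid metabolism showed selected falls. Of 23 lipogenesis genes 5 fell and 1 rose (6 and 3 adjusted over the list alone). Gpam (chromosome 19, 55067268 to 55127238), which starts glycerolipid synthesis, went from 218 ± 12.4 to 46.9 ± 5.08 CPM (log2 fold change -2.22 ± 0.28, adjusted p = 0.00838), Elovl6 (chromosome 3, 129532355 to 129638495) had a log2 fold change of -3.32 ± 0.48, and Fasn and Acly of -2.52 ± 0.49 and -2.00 ± 0.30. The riser was the lipid droplet gene Cidec (chromosome 6, 113424634 to 113435760), at 213 ± 166 CPM in treated livers (log2 fold change 6.30 ± 0.83, adjusted p = 0.00869). Gpam, Elovl6 and Cidec held in all leave-one-out fits. Of 22 gluconeogenesis and glycolysis genes 6 fell and 0 rose (6 and 1 adjusted over the list alone), among them Pfkfb1 (chromosome X, 150588229 to 150643878; log2 fold change -3.45 ± 0.48, adjusted p = 0.00929, held in all leave-one-out fits), Pklr (chromosome 3, 89136142 to 89146784; -1.89 ± 0.38) and the glucose-6-phosphatase gene G6pc (chromosome 11, 101367561 to 101377903; -2.80 ± 0.68). Of 22 urea cycle and amino acid breakdown genes 4 fell and 0 rose (4 and 0 adjusted over the list alone). Otc (chromosome X, 10252305 to 10321024), an enzyme of the urea cycle, went from 644 ± 21.5 to 45.1 ± 35.1 CPM (log2 fold change -3.84 ± 0.69, adjusted p = 0.0150), and Hal (chromosome 10, 93488768 to 93519304), which breaks down histidine, was at -3.54 ± 0.55. Of 24 phase II conjugation genes 4 fell and 0 rose (1 and 0 adjusted over the list alone), including Tpmt (chromosome 13, 47022482 to 47044737; log2 fold change -2.25 ± 0.35, adjusted p = 0.0113) and Sult1b1 (-2.19 ± 0.56). Tpmt lost its call without control 2, and Hal lost its call without bortezomib 2 or control 2, Otc without these or control 1, and Pklr without these, control 1 or bortezomib 1. Camera adjusted p was 0.0483, 0.0205, 4.2e-04 and 0.00155 for the lipogenesis, sugar, urea cycle and phase II lists. The matching values were adjusted p = 0.649 for the sugar list and adjusted p = 0.621 for the other 3, each with an estimated correlation. Bortezomib 3 had the lowest medians in these 4 lists (-2.06, -2.45, -3.42 and -2.21). The urea cycle list was at -0.55 and -0.87 in bortezomib 1 and 2. The lipogenesis list was not called without bortezomib 3, control 1 or control 2 (medians -0.56, -0.80 and -0.67), nor with RLE scaling (-0.50) or a filter of 1 CPM in 3 libraries (-0.49), and the sugar list was not called without bortezomib 3 or control 2 (-0.46 and -0.68). Neither was called without bortezomib 3 and with the Xist or Y term (-0.84 and -0.61). Without bortezomib 3, 8, 7, 5 and 8 members of the 4 lists fell and 5, 4, 0 and 0 rose. Without any other single library 2 to 4, 1 to 3, 0 to 2 and 0 to 2 fell. G6pc kept its call only without bortezomib 3 (-3.99), and Sult1b1 only without bortezomib 1 (-2.87) or 3. Acly lost its call without bortezomib 1 or 2 or control 1, and Fasn without bortezomib 1 or control 1 or 2. Hal and Otc were at -4.19 and -4.61 without bortezomib 1, and Cidec at 5.60 without bortezomib 2.

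Several hepatic lists had members moving both ways and were not called. Of 30 PPARalpha target and fatty acid oxidation genes 2 rose and 2 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.481). The kinase gene Pdk4 (chromosome 6, 5483351 to 5496309) had a log2 fold change of 4.45 ± 0.99 (adjusted p = 0.0251) and Acot2 of 3.89 ± 0.74, while Bdh1 was at -2.63 ± 0.52. Pdk4 was at 13.4 CPM in bortezomib 3, against 193 and 275 CPM in bortezomib 1 and 2. Of 27 drug-metabolising cytochromes P450 and their receptors 1 rose, Cyp2b10 (log2 fold change 4.34 ± 1.18, adjusted p = 0.0423), and 1 fell, Ahr (-1.50 ± 0.33), with 0 and 0 adjusted over the list alone and camera adjusted p = 0.665. Of 22 circadian clock genes 3 rose and 1 fell (3 and 1 adjusted over the list alone; adjusted p = 0.203): Per1 (1.92 ± 0.37), Cry2 (2.64 ± 0.64) and Wee1 (3.50 ± 0.73) rose and Hlf (-1.73 ± 0.41) fell. The clock list median was 1.19 and 1.26 in bortezomib 1 and 2 and -0.58 in bortezomib 3, and the list was called without bortezomib 3 (median 1.16, and 1.20 with the Xist or Y term as well). Of 24 hepatokine and iron genes 4 rose and 1 fell (7 and 1 adjusted over the list alone; adjusted p = 0.481). Hamp (chromosome 7, 30942368 to 30944032), which encodes the iron hormone hepcidin, was at 2245 ± 198 CPM in treated livers and 211 ± 169.6 CPM in controls (log2 fold change 3.41 ± 0.92, adjusted p = 0.0413), and the stress cytokine gene Gdf15 (chromosome 8, 70629393 to 70632456) was at 4.96 ± 0.78. The albumin gene Alb (chromosome 5, 90460897 to 90476602) was at 69059 ± 33872 CPM in treated livers and 71863 ± 25356 CPM in controls (log2 fold change -0.06 ± 0.61, adjusted p = 0.955). Without bortezomib 3, 5, 4, 13 and 8 members of the PPARalpha, P450, clock and hepatokine lists rose and 3, 2, 2 and 2 fell. Without any other single library 0, 0 to 1, 0 to 1 and 0 to 2 rose and 0 to 3, 0, 0 and 0 to 1 fell. Pdk4, Acot2, Cyp2b10, Ahr, Cry2, Wee1 and Hlf kept their calls only without bortezomib 3, and Bdh1, Per1 and Hamp only without bortezomib 3 or control 3. Gdf15 lost its call without control 1 or 2. Cyp2b10, at 99.5, 140 and 14.4 CPM in bortezomib 1 to 3 and 9.63, 0.475 and 2.37 CPM in controls 1 to 3, had a log2 fold change of 5.88 without control 1, and Pdk4 one of 3.84 without bortezomib 2.

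Several interferon-stimulated genes and macrophage markers fell. Of 33 interferon-stimulated genes 18 fell and 1 rose (23 and 4 adjusted over the list alone), with a median of -1.60. Usp18 (chromosome 6, 121245906 to 121270917), a negative regulator of interferon signalling, went from 16.7 ± 2.37 to 2.94 ± 0.306 CPM (log2 fold change -2.50 ± 0.30, adjusted p = 0.00819). Its call held in all leave-one-out fits, and Ifit3 (chromosome 19, 34583531 to 34588731; -2.50 ± 0.40) lost its call without control 1. The riser was Mx2 (2.96 ± 0.67). Psmb8 and Psmb9 are members of this list too. Of 14 Kupffer cell and macrophage markers 7 fell and 0 rose (12 and 1 adjusted over the list alone), with a median of -1.43. Clec4f (chromosome 6, 83644542 to 83656187), a Kupffer cell lectin, went from 244 ± 58.4 to 66.6 ± 16.9 CPM (log2 fold change -1.88 ± 0.35, adjusted p = 0.0164), and the complement genes C1qa and C1qc had log2 fold changes of -1.44 ± 0.34 and -1.47 ± 0.29. Of 12 T and NK cell markers 1 fell, Cd4 (0.427 ± 0.0531 CPM in treated livers and 3.32 ± 3.02 CPM in controls), and 6 fell adjusted over the list alone, with a list median of -1.51. These 3 lists were called (camera adjusted p = 3.3e-07, 7.0e-04 and 0.00178), with adjusted p = 0.621 for each with an estimated correlation. With a filter of 1 CPM in 3 libraries, which left 5 T and NK cell markers, that list was not called (median -1.87). The interferon list was at -1.33, -1.57 and -1.68 in bortezomib 1 to 3 and at -0.21, -0.27 and 0.58 in controls 1 to 3. Of 18 NF-kB and chemokine genes 4 rose and 0 fell (8 and 0 adjusted over the list alone), among them Cxcl1 (chromosome 5, 90891241 to 90893115; log2 fold change 3.69 ± 0.88, adjusted p = 0.0296) and Relb (2.75 ± 0.65). This list passed narrowly (camera adjusted p = 0.0483, against adjusted p = 0.649 with an estimated correlation). It was at 1.44 and 1.84 in bortezomib 1 and 2 and 0.01 in bortezomib 3. It was not called without bortezomib 1 or 2 or control 2 or 3 (medians 1.14, 0.70, 1.04 and 1.23), nor with RLE scaling (1.25), a filter of 1 CPM in 3 libraries (0.93), the Xist or Y term (1.48) or the 4 libraries with high Xist (1.45). Without bortezomib 3, 20 interferon, 10 macrophage and 4 T and NK cell genes fell (4, 1 and 0 rose) and 11 NF-kB genes rose. Without any other single library these counts were 4 to 12, 0 to 3, 0 and 0 to 2. C1qa, Cd4 and Relb kept their calls only without bortezomib 3, and Clec4f, C1qc, Cxcl1 and Mx2 only without bortezomib 3 or control 3. Cd4 went from a log2 fold change of -2.94 to -1.88 without control 2, and Cxcl1 was at 4.84 without control 3.

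Of 27 acute phase genes 5 rose and 2 fell, and the list was not called (5 and 3 adjusted over the list alone; adjusted p = 0.968). Serpina3m (chromosome 12, 104338486 to 104394257) was at 1271 ± 375 CPM in treated livers and 326 ± 92.6 CPM in controls (log2 fold change 1.96 ± 0.43, adjusted p = 0.0237), Orm3 at 4.08 ± 0.81 and Crp at -1.87 ± 0.41; Serpina3 and Orm genes are multigene families whose reads can be shared. Of 24 secreted hepatocyte proteins 1 passed, Apoa4 (chromosome 9, 46240696 to 46243459), which rose (log2 fold change 4.60 ± 0.83, adjusted p = 0.0153), and 0 fell (1 and 0 adjusted over the list alone), while the list stood lower than other genes (median -0.61, camera adjusted p = 0.0257; adjusted p = 0.738 with an estimated correlation). That list was at -1.62 in bortezomib 3 and was not called without it (median -0.41, and -0.46 with the Xist or Y term as well) or without control 2 (-0.52). The lists of genes of hepatocytes near the central vein and near the portal tract stood lower in camera with a preset correlation. Neither was called with an estimated correlation or without bortezomib 3. Of 20 pericentral genes 4 fell (4 adjusted over the list alone), among them the Wnt target genes Lgr5 (chromosome 10, 115450311 to 115587780; log2 fold change -2.67 ± 0.42, adjusted p = 0.0113) and Notum (-3.20 ± 0.49), and Aldh1a1 (-2.67 ± 0.50), which was at 569 CPM in control 1 against 1633 and 1411 CPM in controls 2 and 3. Of 20 periportal genes 4 fell and 2 rose (6 and 2 adjusted over the list alone). Hal, Aldh1b1, Etnppl and Ctsc fell, and Apoa4 and the lipid transporter gene Mfsd2a (4.58 ± 1.02) rose. Camera adjusted p was 0.00180 for the pericentral list and 0.00698 for the periportal list, with adjusted p = 0.621 and adjusted p = 0.649 with an estimated correlation. Their medians were -2.51 and -2.85 in bortezomib 3, and neither list was called without it (-0.73 and -0.68). The periportal list was also not called without it and with the Xist or Y term (-0.996). Without bortezomib 3, 5, 1, 5 and 6 members of the acute phase, secreted, pericentral and periportal lists fell and 5, 1, 1 and 2 rose. Without any other single library 0, 0, 1 to 3 and 0 to 2 fell and 0 to 1, 0 to 1, 0 and 0 to 1 rose. Serpina3m, Orm3, Crp, Ctsc, Etnppl and Mfsd2a kept their calls only without bortezomib 3, and Apoa4 only without bortezomib 2 or 3. Lgr5 lost its call without bortezomib 1, Notum without control 1 or 2, Aldh1a1 without bortezomib 1 or 2 or control 2, and Aldh1b1 without bortezomib 2 or control 1 or 2. Mfsd2a was at 5.36 without control 1.

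Of 34 nuclear genes of oxidative phosphorylation 3 fell and 0 rose (0 and 0 adjusted over the list alone): Sdhc (log2 fold change -1.38 ± 0.33, adjusted p = 0.0303), Ndufb3 and Ndufb10 (-1.24 ± 0.28 and -1.26 ± 0.34). Of all 15375 tested genes 1231 fell, so this count was near the overall share. The list had a median of -0.55 and was called (camera adjusted p = 8.4e-04; adjusted p = 0.621 with an estimated correlation). Of 7 red cell and erythroid genes 2 fell, Bpgm (-1.04 ± 0.27) and Alas2 (-2.90 ± 0.76), with 4 adjusted over the list alone. Alas2 was at 18.2 CPM in control 1, against 133 and 66.6 CPM in controls 2 and 3. The erythroid list was called (adjusted p = 0.0163; adjusted p = 0.621 with an estimated correlation), but not without bortezomib 3 (median -1.46, from -1.82), with the Xist or Y term (-0.98) or with both changes (-0.75). Of 13 sinusoidal endothelial markers 1 rose, Lyve1 (2.65 ± 0.44), and 2 fell, Fcgr2b and Ehd3 (-1.77 ± 0.29 and -1.88 ± 0.29). Adjusted over the list alone 2 rose and 6 fell. Camera did not call the list (adjusted p = 0.140), while fry did (fry adjusted p = 0.0228). Of 7 cholangiocyte markers 1 rose, Sox9 (4.86 ± 1.13, with 5.29 CPM in bortezomib 3 and 168 and 188 CPM in the other treated libraries) and 1 fell, with 1 and 2 adjusted over the list alone. Camera did not call that list (adjusted p = 0.519), while fry did (fry adjusted p = 0.0228). Of 22 matrix genes 3 rose and 2 fell (4 and 2 adjusted over the list alone; list adjusted p = 0.998). Col4a1 rose (2.24 ± 0.46) and Col3a1 fell (-1.61 ± 0.34). Without bortezomib 3, 6, 3, 6, 4 and 2 members of these 5 lists fell and 0, 0, 3, 1 and 6 rose. Without any other single library 0 to 1, 0 to 1, 0 to 2, 0 and 0 to 1 fell and 0, 0, 0 to 1, 0 and 1 rose. Ndufb3, Ndufb10, Bpgm, Sox9 and Col4a1 kept their calls only without bortezomib 3, Sdhc and Col3a1 only without bortezomib 3 or control 3, and Alas2 only without bortezomib 3 or control 1. Lyve1 lost its call without control 1 or 2, Ehd3 without these or bortezomib 2, and Fcgr2b without control 1 or bortezomib 1 or 2. Alas2 was at -2.11 without control 2.

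In edgeR no member passed among the 12 hepatocyte, 13 stellate cell and 8 neutrophil markers, the 49 ribosomal protein genes and the 15 mitochondrially encoded transcripts, over all genes or adjusted over the list alone. Their list medians were -0.56, 0.39, 1.40, 0.22 and -0.34, and none of these 5 lists was called (adjusted p = 0.209, 0.654, 0.0626, 0.0551 and 0.272). At an unadjusted p under 0.05 edgeR had 1, 1, 3, 2 and 1 members of them, DESeq2 called 1, 0, 1, 0 and 1, and limma-voom 0 in each. The neutrophil list was called without bortezomib 3 (median 1.58), without control 3 (1.52), with the Xist or Y term (1.50, and 1.66 without bortezomib 3 as well) and in the 4 libraries with high Xist (1.58). The ribosomal protein list was called with no low-count filter (0.21), without bortezomib 2 (0.33) or control 3 (0.40), with the replicate block (0.23) or the Xist or Y term (0.37) and in the 4 libraries with high Xist (0.33). Of 26 genes of S and G2/M phase Mcm6 rose (1.56 ± 0.30) and Birc5 fell (-2.53 ± 0.70), with 1 and 0 adjusted over the list alone and adjusted p = 0.725 for the list. The remaining marker lists, of monocytes, B and plasma cells, platelets, mesothelium and adipose tissue, and pancreas, gut and gall bladder, had 8, 8, 3, 6 and 4 tested members and were not called (adjusted p = 0.0842, 0.998, 0.381, 0.461 and 0.0842). The monocyte list was called with no low-count filter (median -0.85), the replicate block (-0.70) or without control 2 (-1.17), and the pancreas and gut list with library totals (-1.41) or without bortezomib 1 (-1.76). Each had 1 member past the test: Ly6c2 (-2.71 ± 0.58), Jchain (-2.36 ± 0.50) and Cela1 (-3.01 ± 0.52) fell, and Itga2b (1.40 ± 0.38) and Cidec rose. Adjusted over the list alone, 2 monocyte, 1 B cell and 2 pancreas and gut members fell, 1 platelet member rose, and 1 mesothelium and adipose member rose and 1 fell. For 6 lists that were not called the median, the mean and the direction of the test differed in sign: the median and mean log2 fold changes were 0.17 and -0.04 for S and G2/M genes, 0.04 and 0.10 for PPARalpha targets, -0.15 and 0.19 for acute phase genes, -0.85 and 0.09 for cholangiocyte markers, 0.11 and -0.07 for B and plasma cell markers (tested direction lower in these 5), and -0.06 and 0.40 for matrix genes (tested direction higher). Without bortezomib 3, 6 neutrophil, 1 stellate and 5 S and G2/M genes rose, and 2 stellate, 2 S and G2/M, 1 mitochondrial and 3 monocyte genes fell. Without control 3, 1 ribosomal protein and 1 neutrophil gene rose. Mcm6, Birc5, Ly6c2 and Jchain kept their calls only without bortezomib 3, and Itga2b only without bortezomib 3 or control 3. Cela1 lost its call without bortezomib 2 or control 1 or 2, and was at -3.60 without bortezomib 1.

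Several male-biased liver genes fell in treated livers, along with the sex-linked pattern. Of 24 tested, 8 fell and 0 rose (17 and 0 adjusted over the list alone), with a median of -3.62 and camera adjusted p = 1.4e-05 (adjusted p = 0.621 with an estimated correlation). With the Xist or Y term the median was -0.32 and the list was not called, nor was it in the 4 libraries with high Xist (-0.35) or with the term and bortezomib 3 left out (0.0018). Elovl3 (chromosome 19, 46131897 to 46135694), a fatty acid elongase, had a log2 fold change of -9.15 ± 2.13 and was at 2.27, 1144 and 77.4 CPM in controls 1 to 3 and at 0.709 ± 0.0712 CPM in treated livers. The steroid dehydrogenase gene Hsd3b5 (chromosome 3, 98618634 to 98630252; -7.84 ± 1.87) was at 1.93, 348 and 76.6 CPM in controls 1 to 3. The urinary protein genes Mup1, Mup7, Mup12 and Mup20, whose family members share reads, fell with the same pattern, Mup7 being at 4.20, 3131 and 3352 CPM in controls 1 to 3. Keg1 (chromosome 19, 12695786 to 12719902; log2 fold change -6.92 ± 1.01, adjusted p = 0.0103) was at 27.8 CPM in control 1 and 0.791 ± 0.566 CPM in treated livers, and its call held in all leave-one-out fits. Of 26 female-biased genes 0 passed in edgeR, also adjusted over the list alone (1 at an unadjusted p under 0.05, 1 called by DESeq2 and 0 by limma-voom), and the list was not called in the main test (median 0.07, adjusted p = 0.0966), but it was called higher without control 1 (median 4.32) and with the replicate block (1.37), and lower with the Xist or Y term (-1.01) and in the 4 libraries with high Xist (-1.05). Without control 1, 8 male-biased genes fell, without bortezomib 3, 4, and without any other single library 1 or 2. Elovl3, Hsd3b5 and the 4 Mup genes kept their calls only without control 1. Without control 2, Elovl3, Hsd3b5 and Keg1 were at -5.78, -5.97 and -5.92. Without control 1 the fall of both Elovl3 (-9.76) and Hsd3b5 grew by over 1.5 times, and Hsd3b5 was at -8.95 without bortezomib 2. Of the female-biased genes 2 rose without control 1 and 1 fell without control 2. As defined, the P450, phase II conjugation, bile acid synthesis, bile acid transport and integrated stress response lists share members with the male- or female-biased list. The sex-linked pattern may therefore enter the results of those lists too, which was not tested.

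**Figure D3:**
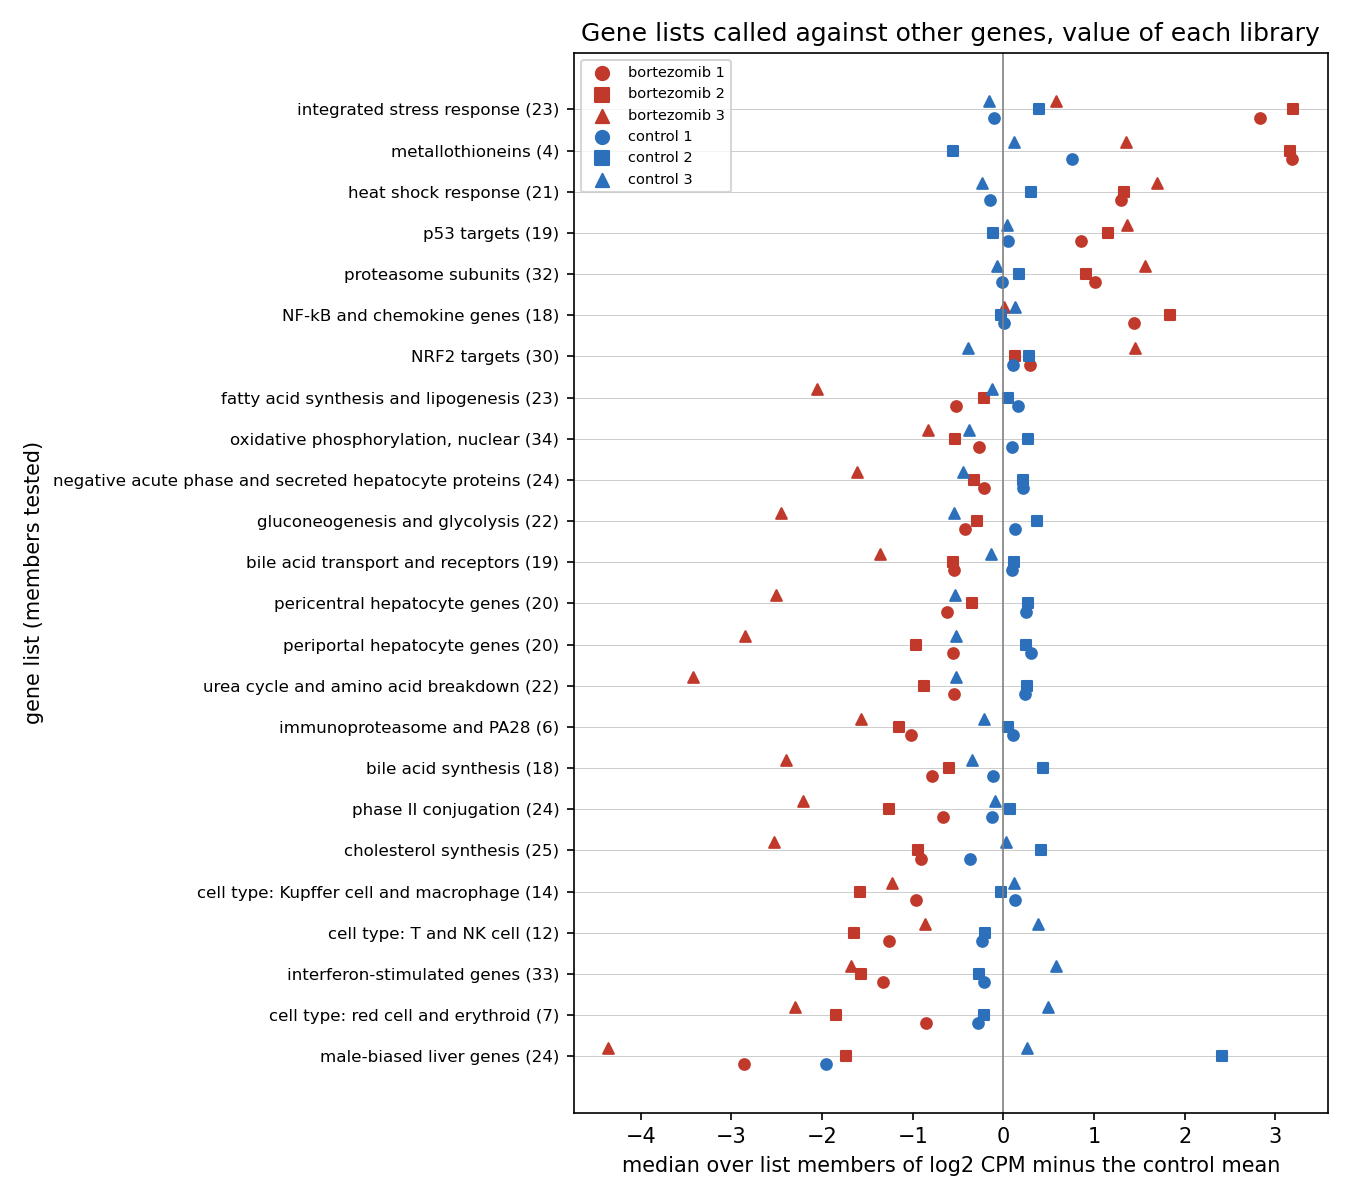
Median over the tested members of log2 CPM minus the control mean, for each library (points, coloured by group with a marker per replicate number), in the 24 gene lists called against other genes with a preset correlation; members tested are in parentheses. The integrated stress response list lies at 2.83 and 3.20 in bortezomib 1 and 2 and at 0.58 in bortezomib 3, and control 1 lies at -1.96 for male-biased genes.

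The rule for the largest changes named 8 genes that rose and 8 that fell. Among the rises were Sprr1a (chromosome 3, 92483952 to 92485895), a cornified envelope protein gene, at 32.7 ± 11.9 CPM in treated livers and 0.0828 ± 0.0841 CPM in controls (log2 fold change 8.46 ± 0.72, adjusted p = 0.00551), and the protease inhibitor gene Wfdc3 (chromosome 2, 164731180 to 164745931; log2 fold change 7.31 ± 0.94, adjusted p = 0.00861), both held in all leave-one-out fits, besides Gsta1 and Atf3. The other 4 had 1 to 3 counts over the 3 controls, so their ratios carry a counting interval only. Bmp8a (chromosome 4, 123312645 to 123343252) had 624 counts against 1, with 24 of them in bortezomib 3, a ratio of 572 (95% interval 102 to 22611). Nyx (chromosome X, 13466110 to 13489313) had 462 against 2, with 407 of them in bortezomib 3, a ratio of 212 (58.2 to 1752), and the AP-1 gene Fosl1 (chromosome 19, 5447547 to 5455946) 398 against 2, a ratio of 182 (50.1 to 1510), with a call held in all leave-one-out fits. Leaving out 1 library moved the log2 fold change of Fosl1 between 6.74 and 10.1, and its 2 control counts were both in control 3. Tub (chromosome 7, 108950338 to 109034460) had 630 against 3, with 11 of them in bortezomib 3, a ratio of 192 (65.5 to 935). The call was lost without control 1 or 2 for Bmp8a, without any of the controls for Nyx, and without any of the controls or bortezomib 1 for Tub. The falls were Elovl3, Hsd3b5, Keg1, Nr0b2 and 4 more. Tff3 (chromosome 17, 31125306 to 31129646; -6.28 ± 1.46) was at 2.06 CPM in control 1 and at 116 and 114 CPM in controls 2 and 3. Hsd3b2 (chromosome 3, 98709255 to 98724543; log2 fold change -6.05 ± 0.99, adjusted p = 0.0127) belongs to a family with near-identical copies. Hectd2os (chromosome 19, 36614052 to 36705641; log2 fold change -5.99 ± 0.51, adjusted p = 0.00551) is antisense to Hectd2, and whether the counting used strand was not given in the sources used here. Ppp1r3c (chromosome 19, 36731731 to 36736653), a glycogen-targeting phosphatase subunit gene, went from 147 ± 73.2 to 2.77 ± 2.24 CPM (log2 fold change -5.73 ± 0.73, adjusted p = 0.00844). The calls of Hectd2os and Ppp1r3c held in all leave-one-out fits. Tff3 kept its call only without control 1, and Hsd3b2 lost its call without bortezomib 2 or control 2. Sprr1a was at 9.35 without control 1, Wfdc3 and Ppp1r3c at 6.15 and -6.65 without bortezomib 3, and Tff3 and Hsd3b2 at -7.41 and -6.88 without bortezomib 1.

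**Figure D4:**
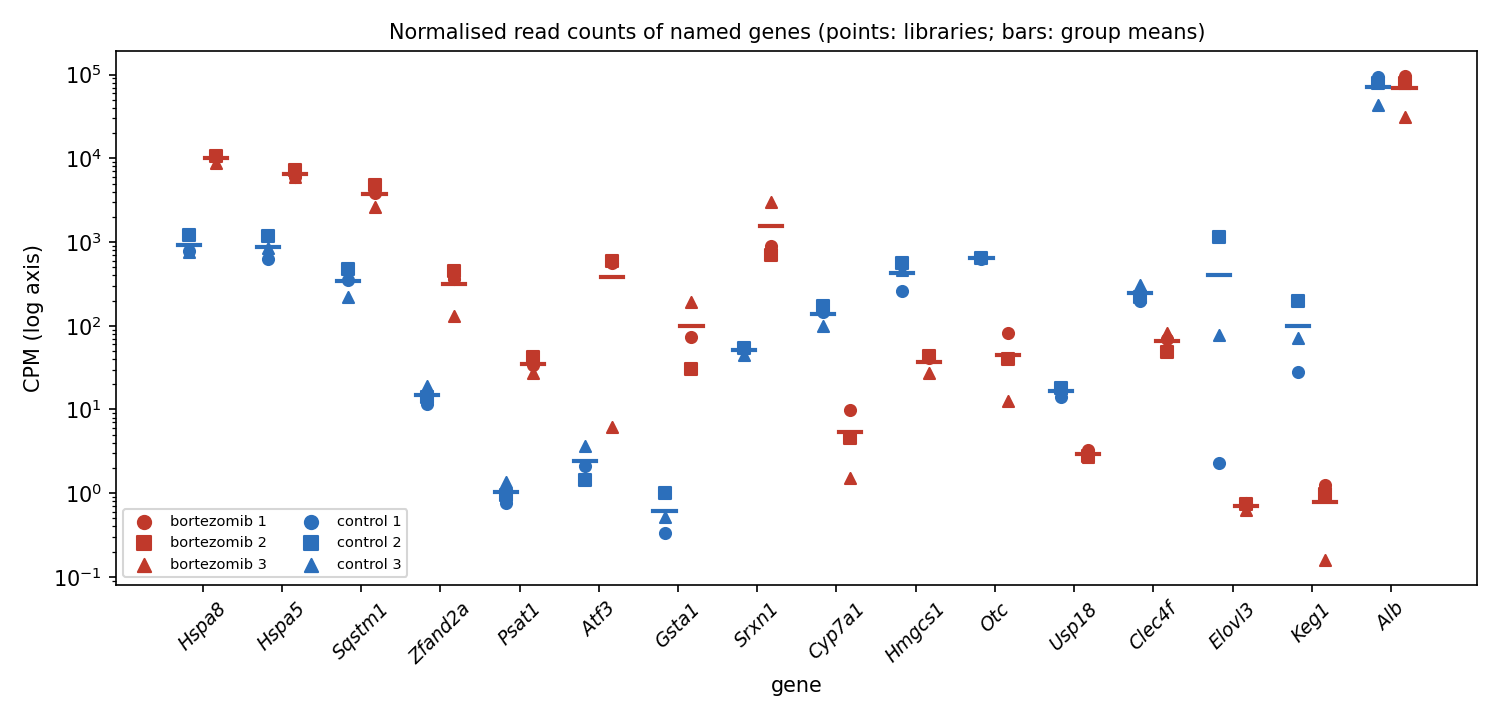
CPM (log axis) of 16 named genes in the 3 control and 3 bortezomib libraries (points, with a marker per replicate number) and the group means (bars). Hspa8 lies between 8799 and 10589 CPM in treated livers and between 760.0 and 1205 CPM in controls, Atf3 in bortezomib 3 is at 6.23 CPM, and Elovl3 in control 1 is at 2.27 CPM.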

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

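The Xist or Y terms, the 4 libraries with high Xist and the recovered reads were chosen after seeing the data. Against 2862 genes changed (1631 higher, 1231 lower), DESeq2 called 4588 (2452 and 2136), an adjusted p under 0.01 left 200 (108 and 92), and library totals called 830 lower. Leaving out 1 library at a time gave 330 to 6702 genes, 112 to 3304 higher and 209 to 3398 lower. The lowest total came without control 1 and the highest without bortezomib 3, the library that stood apart. All of the 2862 genes kept their direction in each of these fits (100%), though they were chosen with all libraries. With the Xist or Y term edgeR called 0 genes (0 higher, 0 lower; 2798 at an unadjusted p under 0.05, lowest adjusted p 0.101), limma-voom 0 (0 and 0; 2898) and DESeq2 1180 (651 and 529). In edgeR the median absolute log2 fold change of the 2862 genes was 1.92 without and 1.96 with the term. The median SE went from 0.406 to 0.625, and 2266 of the genes had an unadjusted p under 0.05 with the term. All treated libraries had high Xist, so the term sets them against control 1 alone. The 2862 genes were chosen with control 1 among the controls. The kept size therefore cannot show that the folds hold apart from the pattern. The term with bortezomib 3 left out, with a median SE of 0.481, called 3145 (1470 and 1675). The 4 libraries with high Xist, with a lone control assumed to vary like the treated libraries, gave 0 genes in edgeR (0 higher, 0 lower; 2657 at an unadjusted p under 0.05). Other scalings, filters and tests kept the total within 1.5 times, such as 2723 with upper quartile scaling, 2492 with library totals, 3051 with no filter and 2887 with limma-voom.

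Of 47 lists, 24 were called, 16 to 25 without 1 library and 0 with an estimated correlation. In simulation a list shifted 2-fold was also missed with an estimated correlation (camera adjusted p = 0.0682). The proteasome list kept its call in its alternatives but the estimated correlation (median 1.25, adjusted p 0.621), with a median of 0.93 to 1.42 without 1 library. Of the 24 lists, 8 kept the call in each alternative but that one. The female-biased list, at 0.07, reversed to -1.01 with the Xist or Y term and -1.05 in the 4 libraries with high Xist. Both settings compare the treated libraries with control 1 alone. Its list median was 3.63, against -2.79 and -0.85 in controls 2 and 3 and 3.25, 1.96 and 0.12 in bortezomib 1 to 3. The reversal thus came with the change of reference. The high level in control 1 is taken up below, where female animals remain a candidate explanation found and tested on the same data. The replicate block gave 2174 genes (1119 and 1055) and 28 lists. Same-numbered libraries had correlated deviations of 0.0654, 0.214 and 0.183, and each treated library correlated best with its same-numbered control. Differently numbered pairs lay between -0.278 and 0.103. The same-numbered values were not all over 0.1, and control 1 correlated best with bortezomib 2 (0.103). The numbers were therefore not taken to pair the samples, though a pairing is not excluded. These are the numbers of the titles. The deposited count columns of controls 2 and 3 are numbered 3 and 4, so by column bortezomib 3 would share its number with control 2, and their deviations correlated at -0.112. With 3 libraries per group, 4-fold changes were recovered at 44% in simulation and 2-fold changes at 0%. At 50% of the simulated spread these were 98% and 58%. The simulation changed 200 genes, against 2862 called in the data, and fewer changed genes make the adjusted threshold stricter. Its recovery may thus be too low for these data. Changes near 2-fold can still be missed, though single genes such as Bpgm (-1.04 on the log2 scale) passed.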

Other observations

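Further gene groups were chosen after the gene results were seen, so counts and medians describe them and no set test is given. Over all 15375 tested genes 1631 rose and 1231 fell, which is the background for these counts. Of 24 ribosome biogenesis and nucleolar genes 14 rose and 0 fell (17 and 0 adjusted over the list alone), with a median log2 fold change of 1.36. Without bortezomib 3, 17 rose, and without any other single library 2 to 6 did. Nop58, a core protein of small nucleolar particles, rose by 2.66 ± 0.27 on the log2 scale, the nucleolar gene Gnl3 by 2.84 ± 0.36 and Utp20, of small-subunit processing, by 1.81 ± 0.25. Utp20 lost its call without control 1, and the other 2 held in all leave-one-out fits. The list median was 1.25, 1.57 and 1.26 in bortezomib 1 to 3. Of 19 AP-1 and immediate early genes 13 rose and 0 fell (14 and 0 adjusted over the list alone), with a median of 4.33. Without bortezomib 3, 17 rose, and without any other single library 2 to 8 did. Bortezomib 3 differed here, with a list median of 1.68 against 4.45 and 4.38 in bortezomib 1 and 2. Gadd45a was at 634, 638 and 12.7 CPM and Jun at 208, 329 and 27.1 CPM in bortezomib 1 to 3, and both kept their calls only without bortezomib 3. Ier3 was at 12.1, 13.2 and 14.1 CPM, and its call held in all leave-one-out fits. With the Xist or Y term edgeR called 0 members of either list, whose medians were then 1.34 and 4.78.

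Of 20 hepatocyte transcription factor genes 3 fell and 0 rose (6 and 0 adjusted over the list alone): Onecut1 (-2.80 ± 0.63), Prox1 (-1.46 ± 0.26) and Nr5a2 (-1.73 ± 0.27), with a list median of -0.73. Without bortezomib 3, 9 fell and 3 rose, with a median of -0.88. The 3 genes kept their calls only without bortezomib 3 or control 3, and Onecut1 was at -3.42 without bortezomib 2. Without control 3, 4 fell, and without any other single library or with the Xist or Y term 0 did. Of 20 cytosolic aminoacyl-tRNA synthetase genes 4 rose (5 adjusted over the list alone; median 0.47), and of 13 chaperonin and prefoldin genes 2 rose, Cct2 and Cct7 (2 adjusted over the list alone; median 0.63). Without bortezomib 3, 6 and 2 rose (0 and 1 fell), with medians of 0.40 and 0.32, and without any other single library, or with the Xist or Y term, 0 did in either. Of 12 tubulin genes 1 rose, Tubb6 (3.13 ± 0.29), whose call held in all leave-one-out fits, and 3 fell (2 and 3 adjusted over the list alone). Without bortezomib 3, 2 tubulin genes rose and 4 fell, and without any other single library 1 rose and 0 fell.

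Among the tests below, those of GC content and length, of the hepatocyte share, of male-biased genes as a part, and all 3 on the Xist and Y pattern were chosen after the result was seen. The first pattern is the count of genes changed by bortezomib. Splits of 3 against 3 libraries number 10 and cannot give a share under 0.05. Of the 10 splits 1, the real one, gave 2862 genes and the highest other 0 in edgeR (up to 1518 at an unadjusted p under 0.05). Each other split mixes treated and control libraries, so a difference between treatments widens the spread within its groups. The contrast of 2862 with 0 therefore does not decide whether chance gave the count. If the sex-linked pattern stood in for treatment, control 1 would lie with the treated libraries, but over 317 of the 330 genes called without control 1, those also tested with all libraries, its median position was 0.961 (quartiles 0.799 to 1.08), where 0 is the treated mean and 1 the mean of controls 2 and 3, which argues against that pattern as the whole source of the count. Over the 24 male-biased genes the median position was 0.173 (quartiles -0.0212 to 0.338), so the fall of these genes may come from the sex-linked pattern and not from treatment.

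The second pattern is the distance of bortezomib 3 from bortezomib 1 and 2, an SD of 1.25 over 8528 genes on the log2 scale, against 0.425 between bortezomib 1 and 2. Depth was argued against, since bortezomib 1 thinned to the total of bortezomib 3 had an SD of 0.428 from bortezomib 2, and so was a trend on GC content and length, whose removal left an SD of 1.23. A lower share of hepatocytes would raise the markers of all 6 other cell types, and 4 of the 6 medians were lower in bortezomib 3. Quartiles spanned 0 for cholangiocyte (-0.62 to 1.75), Kupffer cell (-0.73 to 0.73), sinusoidal endothelial (-0.60 to 0.33) and stellate cell markers (-0.50 to 1.05). Neutrophil markers (median -0.71, quartiles -2.54 to -0.31) moved apart from T and NK cell markers (0.42, 0.07 to 0.81). With most quartiles spanning 0, the medians do not decide whether that share was lower. Of 6299 genes called without bortezomib 3, 81.3% went the same way in it and 49.7% changed by at least 50% as much on the log2 scale. The design gives no group that sets bortezomib 3 apart, and a difference in dose, time or condition of that animal stays open as untested.

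The third pattern is high Xist with almost no Y-linked transcript in the 3 treated libraries and control 1, in mice described as male. Whether the mice or the description differ was not tested, but a treatment effect on these transcripts is argued against by control 1, which was not treated and had 0.240% of the Y-linked level of the lower of controls 2 and 3. An exchange of control 1 with a treated library is argued against by Hspa8, which in control 1 was at 8.91% of the lowest treated library. Female animals remain a candidate explanation, found and tested on the same data. At 49 of 50 sex-biased liver genes (98%), control 1 lay below both controls 2 and 3 for a male-biased gene or above both for a female-biased one. For a single gene chance gives 1 in 3. Genes of the male- and female-biased lists moved together (estimated correlations 0.734 and 0.738), so the 49 are not independent observations. Bortezomib 3 had a female-biased list median of 0.12 relative to the control mean, against 3.25 and 1.96 in bortezomib 1 and 2.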
